A study of Arabidopsis thaliana with 12 samples.

How the data were processed

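The series holds 12 expression arrays of total RNA from wild-type Arabidopsis thaliana, 6 from samples in water and 6 from samples given staurosporine and then ascorbate. Groups and replicate numbers were taken from the sample titles. The deposited table holds 1 linear intensity per row and array. How the authors scanned, corrected for background and scaled these intensities is not given in the sources used here. From the values, the deposited intensities are never negative, have means near 1 on each array and reach a highest value just under 100. Between 10.3% and 15.2% of the values of an array are exactly 0, and 123 rows are at 0 on all 12 arrays. What a 0 stands for is not stated, and signal over background is unknown.

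Values of 0 were set to the 1st percentile of all positive intensities (0.0157), called the floor here, and all values were taken to log2. Positive values under 0.0157 were kept, so they lie below the value given to a 0. The array medians then ranged over 0.47 on the log2 scale, from -1.51 to -1.04. This is more than the 0.1 set beforehand as the limit for a table already normalized between arrays, so the log2 values were quantile-normalized. This step makes the distributions of all arrays equal and would hide a change of most RNAs in one direction. The groups were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, group as the only term and Benjamini-Hochberg adjustment over 3439 rows, with a threshold of 0.05. Fold changes are on this floored and normalized log2 scale, treated minus water, whereas group means are of the intensities as deposited. No filter on low values was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

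Rows were named through the platform annotation held with the series and through gene names of the TAIR10.1 assembly. Of 3439 rows, 692 had a single gene, 870 had several and were given no gene name, and 1877 were not listed and are unnamed here. Of the rows with a single gene, 690 matched a locus, 689 of them distinct. The platform annotation can be old, and no coordinates are printed because the build behind it is not given. The 7 photosynthesis rows with a single gene had a median brightness percentile of 87.3, against 55.0 for the 2 rows with several genes all in the photosynthesis lists and 50.5 for all rows with a single gene.

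Before the data were examined, 23 gene lists with 460 genes, the tests, the alternatives and the rule for named genes were fixed. The lists covered photosystem I, photosystem II, light-harvesting proteins, electron carriers and ATP synthase, the Calvin cycle, photorespiration, tetrapyrrole and isoprenoid synthesis, starch and sugar phosphates, plastid ribosomal proteins and protein import, peroxide and superoxide removal, ascorbate and glutathione, thioredoxins, glutathione transferases, chaperones, proteases, jasmonate and defence, shikimate, nitrogen and sulfur, and housekeeping and root markers. Of these genes, 21 were measured on a row with a single gene. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, which left 1 list, the plastid ribosomal proteins. The rule named the 12 largest rises and 12 largest falls among rows past the threshold with a single gene, a mean above the lowest 25% of rows and groups that did not overlap (120 rows qualified), up to 4 members of each list by smallest p, and the antioxidant genes as a group.

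The same numbers occur in both groups, so it was checked whether they pair the samples. Deviations from the group means of same-numbered water and treated arrays correlated between 0.302 and 0.425. Each was over the limit of 0.1, so the numbers were treated as pairing the samples. Water and treated arrays with adjacent numbers also reached 0.336, and the best treated partner had the same number for only 5 water arrays. The check therefore cannot tell paired samples from handling shared by same-numbered or adjacent arrays. The pairing comes from this check, since the labels do not state what a number stands for. The main test kept group as the only term, as fixed beforehand, and a fit with the replicate number as a block was an alternative.

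Alternatives fixed beforehand were the table as deposited, median centring, a floor at the 10th percentile, a pseudocount of 0.0512, a filter on dim rows, a variance model with trend, array weights, the replicate block, an exact rank-sum test, each array left out in turn, and replicates 1 to 3 or 4 to 6 alone. Added after the data were examined were the sets of adjacent arrays as means, as random or fixed blocks and alone, scaling before the floor, and rows above 0 on all arrays. Unlike the main floor, the floor at the 10th percentile and the floor after scaling were also given to lower positive values. In simulated data with 200 of 3439 rows changed and independent arrays, tested in 10 runs, 5.71% of calls in the 6 against 6 comparison were false, and 60.4% of rows changed by 1 on the log2 scale and 83.2% of those changed by 2 were recovered, against 39.2% and 69.2% on means of sets. When arrays of a set were simulated with the correlation estimated from these data, 30.0% of calls were false with 6 against 6 arrays, and 4.95% on means of sets, which recovered 21.8% of rows changed by 1 and 55.4% of those changed by 2. This simulation gave the sets of the 2 groups separate deviations, whereas here arrays of the same number also correlated across groups. It also changed far fewer rows than the 1131 called here, so its shares of false calls are not estimates for these counts. For the list test, 20 of 20 simulated runs called a list of 7 members all shifted by 1, and 1 of 20 called an unshifted one. These runs used independent arrays and shifted no row outside the list, whereas 1131 rows were called here. The 7 members also included SBPASE, which is at 0 on all 12 arrays and has almost no spread. The runs therefore do not give the power of the list tests on these data.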

Results

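RNA levels were measured on expression arrays in wild-type Arabidopsis thaliana of the Columbia 0 ecotype. Total RNA from 6 samples kept for 8 h in water was compared with total RNA from 6 samples given 2 µM staurosporine for 4 h and then 25 mM ascorbate at pH 5.5 for 4 h. Staurosporine is a broad inhibitor of protein kinases, and ascorbate is the main water-soluble antioxidant of plant cells. The samples carry replicate numbers 1 to 6 in both groups, and the labels name neither the tissue nor where the replicates came from, so p-values measure the spread between these samples, which may be technical. No group received either compound alone, and none received a solution at pH 5.5 without ascorbate. The 2 compounds, their order and this pH were therefore tested only together. Each array gave intensities for 3439 rows of the table, with a mean between 0.857 and 1.04 and between 10.3% and 15.2% of rows listed at 0. The number of arrays, 6 in each group, limits the precision. A single named gene could be given to 692 rows.

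The comparison asked which RNA levels differed between the treated samples and the water samples. Transcripts of PSAN, a lumenal subunit of photosystem I, fell from an intensity of 1.76 ± 0.310 in water to 0.557 ± 0.0533 after treatment (mean ± SD, n = 6 each). Transcripts of AT3G06200, a guanylate kinase, fell from 7.64 ± 1.29 to 1.37 ± 0.166, and those of AT-HF, an enzyme of histidine synthesis, from 1.87 ± 0.435 to 0.405 ± 0.118. Transcripts of AT5G05400, a disease-resistance protein of the nucleotide-binding and leucine-rich-repeat class, rose from 0.179 ± 0.0406 to 0.573 ± 0.108, and those of AT1G74470, the geranylgeranyl reductase that supplies the phytyl chain of chlorophyll and tocopherol, from 1.34 ± 0.192 to 2.53 ± 0.634. Over the whole table, 1131 of 3439 rows (32.9%) changed at an adjusted p under 0.05 in limma, 573 higher and 558 lower after treatment. Of these, 433 changed by at least 2-fold, 239 higher and 194 lower. With the intensities as deposited, without normalization between arrays, 39.2% of 1075 changed rows were higher, against 50.7% in the normalized values. The groups did not overlap in 681 rows (19.8%), where chance gives 0.216% if the 12 arrays are independent and 10% if the arrays of a set, described next, move as one.

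In their deviations from the group mean, arrays with adjacent numbers (1 and 2, 3 and 4, 5 and 6) correlated above all other pairs of arrays of their group, which the labels do not explain. In their levels this did not hold for treated replicates 3 and 4, which correlated at 0.845. When each such pair, called a set here, was averaged before the test (3 against 3), 418 rows changed, 236 higher and 182 lower, and 406 of them had changed in the same direction with all arrays. With the set also as a block, which pairs the sets of the 2 groups, 211 rows changed, 134 higher and 77 lower. This fit leaves few values to estimate the spread, so a call that it ended may reflect lost power. Both tests were chosen after the data had been examined, and the calls they end are named below.

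**Figure D1:**
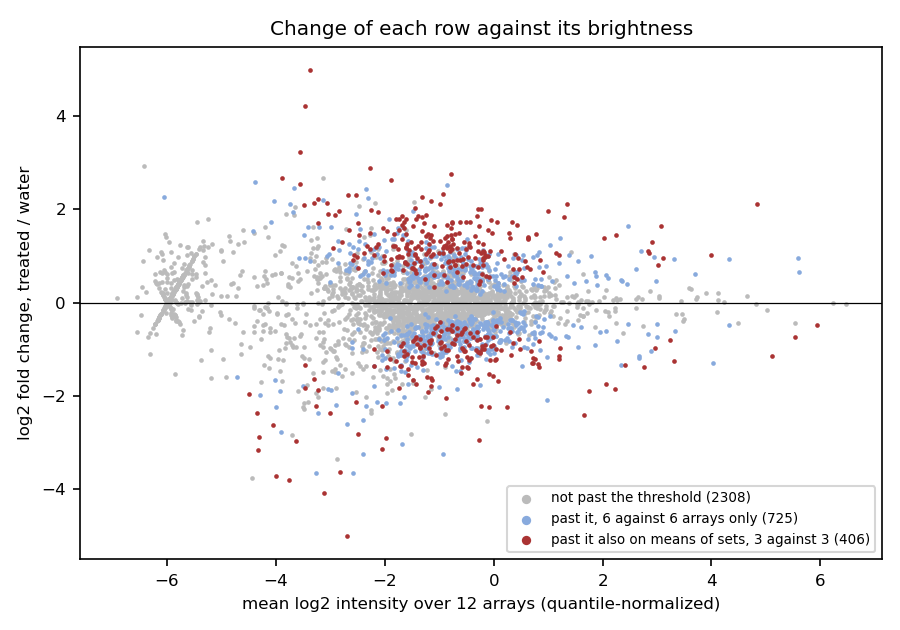
Log2 fold change of each of the 3439 rows (treated over water, vertical axis) against its mean log2 intensity over the 12 arrays (horizontal axis), with quantile-normalized values. Of the 1131 rows past the threshold with 6 against 6 arrays, 406 (dark red) also passed it in the same direction on means of sets, and both rises and falls occurred from dim to bright rows.

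Among the 12 rises chosen by the rule, AT1G58230 had a log2 fold change of 2.23 ± 0.561 (SE), with a limma adjusted p of 0.0104 and of 0.0528 on means of sets. Without water replicate 2, an array far below the others, its log2 fold change was 1.67, below those of the next 2 genes. AT5G05400 followed at 1.85 ± 0.120 (limma adjusted p 1.51e-06) and AT1G34270 at 1.83 ± 0.107 (8.37e-07). AT4G09620 was the brightest of the 12 rises, going from an intensity of 3.71 ± 1.86 to 10.5 ± 1.99, and its adjusted p in limma was 0.000575, or 0.0561 on means of sets, where the sets had log2 fold changes of 0.85, 1.42 and 2.69. AT3G52070 rose from 2.92 ± 0.393 to 7.64 ± 0.952. AT1G67820, a protein phosphatase of the 2C class, rose 3.05-fold, AT3G07790, a protein related to DGCR14, 2.95-fold, AT4G15840 2.88-fold, AT5G52530 2.83-fold and AT2G01400 2.76-fold. AT2G39100 rose 2.56-fold, with an adjusted p in limma of 0.0714 on means of sets and log2 fold changes of 1.44, 0.55 and 2.08 in the sets. AT1G74730, a thylakoid membrane protein, rose 2.50-fold. With replicates 1 to 3 alone, 3 of these 12 rises missed the threshold, and 2 did with replicates 4 to 6 alone. On means of sets, 9 of these 12 rises stayed past the threshold, and 5 did with the set as a block, which also ended the calls of AT3G07790, AT4G15840, AT2G01400 and AT1G74730 (limma adjusted p 0.0533 to 0.0887).

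Among the 12 falls chosen by the rule, AT2G47360 had a log2 fold change of -3.03 ± 0.932 (SE) and a limma adjusted p of 0.0280. It was listed at 0 on both treated arrays of set 2, where the floor sets the size of the fall (log2 fold change -5.85), and stood at -1.91 in set 1 and -1.32 in set 3. Its adjusted p in limma was 0.217 on means of sets and 0.0552, 0.0523 and 0.0555 without water replicate 4, 5 or 6. AT3G06200 fell 5.31-fold (log2 fold change -2.41 ± 0.169, limma adjusted p 2.62e-06) and AT-HF 4.60-fold. Transcripts of CYN, cyanase, which breaks down cyanate, fell 4.22-fold, with an adjusted p in limma of 0.136 on means of sets, and the sets differed, with log2 fold changes of -0.50, -3.03 and -2.71. AT5G19210, a DEAD-box RNA helicase, fell 3.35-fold, with an adjusted p in limma of 0.0709 on means of sets and log2 fold changes of -1.76, -0.82 and -2.65 in the sets. AT4G31210 fell 3.01-fold, PSAN 2.97-fold, AT3G25410, a transporter of the bile acid and sodium symporter family, 2.60-fold, AT5G50350 2.60-fold and AT2G20920 2.59-fold. AT1G24040 fell 2.78-fold and CCL, a transcript under control of the circadian clock, 2.53-fold, with adjusted p in limma of 0.163 and 0.118 on means of sets. Their sets differed in size, with log2 fold changes of -0.86, -0.85 and -2.71 for AT1G24040 and of -0.33, -1.18 and -2.52 for CCL. With replicates 1 to 3 alone, 6 of these 12 falls missed the threshold, CCL with the smallest of them (log2 fold change -0.66, limma adjusted p 0.144), and 2 did with replicates 4 to 6 alone. On means of sets, 7 of these 12 falls stayed past the threshold, and 4 did with the set as a block, which also ended the calls of AT-HF (limma adjusted p 0.0699), AT3G25410 (0.0758) and AT2G20920 (0.0702).

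**Figure D2:**
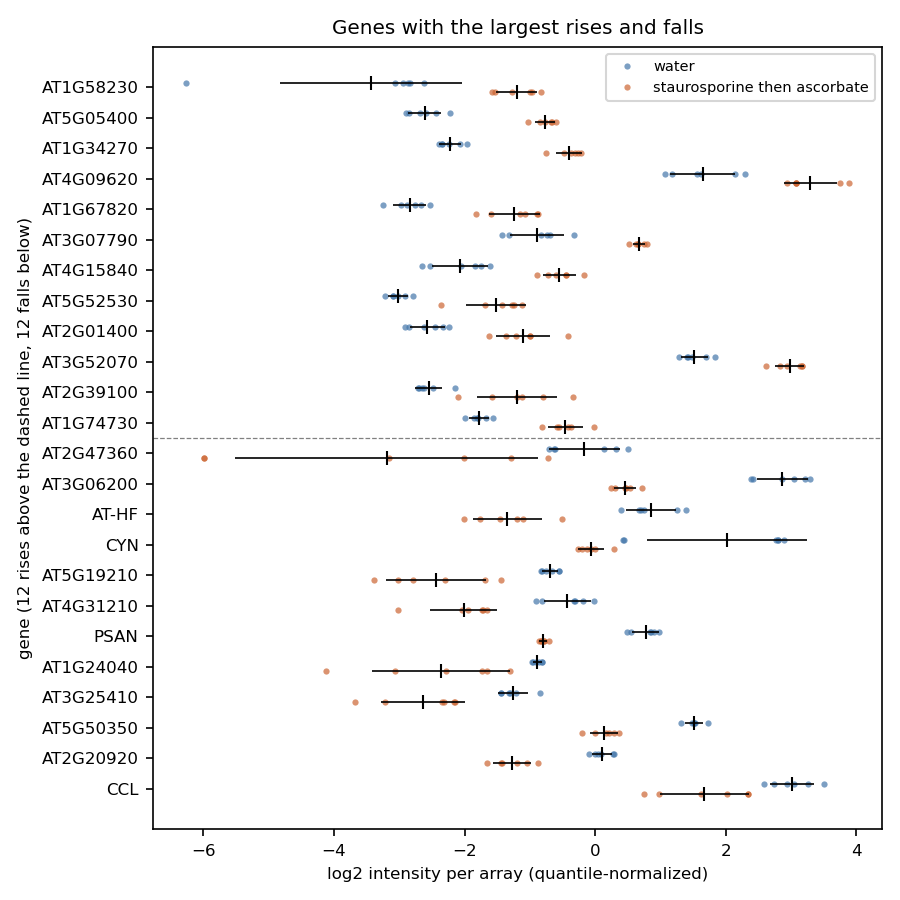
Quantile-normalized log2 intensity on each array (points; blue, water; orange, staurosporine then ascorbate) of the 12 genes with the largest rises and the 12 with the largest falls, with the mean (vertical tick) and SD (horizontal bar), n = 6 in each group. The groups do not overlap in any of the 24 genes, as the rule for choosing them required, a single array lies far from its group for AT1G58230 (water) and AT4G31210 (treated), and 2 treated arrays of AT2G47360 lie at the floor.

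Genes of photosynthesis did not move one way. The single measured gene of the photosystem I list, PSAN, fell (log2 fold change -1.57 ± 0.0856, limma adjusted p 6.96e-07), also on means of sets (0.00755). Of 3 measured photosystem II genes, PSBW, a small subunit of the reaction centre complex, rose from an intensity of 38.0 ± 6.61 to 59.7 ± 18.8, PSBY, another small subunit, fell from 1.21 ± 0.0973 to 0.727 ± 0.128, and PSB27 stood at 1.33 ± 0.542 and 1.16 ± 0.401 (limma adjusted p 0.760). The single light-harvesting gene, LHB1B2, which encodes an antenna protein of photosystem II, fell from 2.18 ± 0.619 to 1.29 ± 0.0867. Adjusted over the list alone, the same genes passed, 1 of 1 in photosystem I, 2 of 3 in photosystem II and 1 of 1 in light harvesting. In a list with 1 measured gene this is the unadjusted p, so for PSAN and LHB1B2 it adds no support. The adjusted p in limma on means of sets was 0.0517 for PSBW, 0.0515 for PSBY and 0.109 for LHB1B2. PSBW also missed the threshold with intensities as deposited (0.0723) and with median centring (0.106), as did LHB1B2 with median centring (0.0508), while the directions of PSBW, PSAN, PSBY and LHB1B2 were the same under each scaling. Of the Calvin cycle genes, PRK stood at 0.641 ± 0.117 and 0.565 ± 0.0831 (limma adjusted p 0.698), and SBPASE was listed at 0 on all 12 arrays, which a failed spot or a wrong annotation of the row would also give, so no level is stated for this usually abundant leaf transcript. CHLM, an enzyme of chlorophyll synthesis, stood at 0.565 ± 0.0842 and 0.464 ± 0.104 (limma adjusted p 0.278).

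Few genes of antioxidant defence were measured on a row of their own. AT3G52960, a plastid peroxiredoxin, was the single measured member of the list for peroxide and superoxide removal. It fell from 0.476 ± 0.0747 to 0.318 ± 0.102 (log2 fold change -0.53 ± 0.157, limma adjusted p 0.0237). Its unadjusted limma p was 0.00634, which adjustment over the list alone, with 1 measured gene, left as it was. Its adjusted p in limma was 0.104 on means of sets, 0.0782 as deposited, 0.0579 with median centring, 0.0590 with the floor at the 10th percentile, 0.0531 without water replicate 5 and 0.279 with replicates 1 to 3 alone. GLDH, which catalyses the last step of ascorbate synthesis, stood at 0.436 ± 0.136 in water and 0.435 ± 0.133 after treatment, and NTRC, a thioredoxin reductase of plastids, at 0.506 ± 0.130 and 0.391 ± 0.128. AT2G04700 stood at 0.129 ± 0.0756 and 0.149 ± 0.0611. None of these last 3 genes passed the threshold with all arrays (limma adjusted p 0.858, 0.330 and 0.493), and adjusted over the list alone none did. NTRC passed with replicates 4 to 6 alone (log2 fold change -1.02, limma adjusted p 0.0152), and its sets differed in sign, with log2 fold changes of 0.33, -0.16 and -1.25.

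Of the remaining lists, plastid ribosomal proteins had 6 measured members, of which 1 fell and 5 did not pass. Among these 5, AT1G64510 was listed at 0 on 5 arrays of each group, so no change can be read for it, though it entered the list test. AT3G13120 fell from 0.330 ± 0.0316 to 0.202 ± 0.0964 (limma adjusted p 0.0299), with an adjusted p of 0.0865 when the replicate number was a block, 0.0943 on means of sets and 0.0518 adjusted over the list alone. This call was also lost as deposited (0.0646), with median centring (0.0583), in the exact rank-sum test (0.0742) and without water replicate 1, 3 or 4 or treated replicate 1 or 4 (0.0510 to 0.0651). Replicates 1 to 3 alone (limma adjusted p 0.168) and replicates 4 to 6 alone (0.272) ended it too. Of the members that did not pass, AT3G54210 stood at 0.702 ± 0.0949 in water and 0.541 ± 0.0884 after treatment (limma adjusted p 0.153, and 0.0356 as deposited). AT5G65220 stood at 1.49 ± 0.321 and 1.82 ± 0.386 and AT1G29070, listed at 0 on 1 array of each group, at 0.0937 ± 0.0590 and 0.236 ± 0.249, and for both the sign of the difference was not the same in the 3 sets. The list as a whole was not called (camera p 0.733, and p = 0.795 with an estimated correlation), and it had no settled direction, with a median log2 fold change of -0.08, a mean of 0.03 and a median between -0.14 and 0.12 when 1 array was left out. AT1G74470, the single measured gene of isoprenoid and tocopherol synthesis, rose 1.88-fold (limma adjusted p 3.12e-05, and 0.0132 on means of sets, but 0.0515 with the set as a block). The nitrogen and sulfur genes APS4 (0.454 ± 0.0862 in water, 0.382 ± 0.118 after treatment) and CBL (0.0931 ± 0.0673 and 0.175 ± 0.131) did not pass (limma adjusted p 0.475 and 0.698). The sign of the APS4 difference was not the same in the 3 sets. CBL passed with replicates 1 to 3 alone (limma adjusted p 0.0380). Its log2 fold change was negative only in set 3 (-0.32), and this sign depends on the floor. There the intensities were 0 and 0.0237 in water and 0.0535 and 0.00561 after treatment. The 0 was raised to the floor, whereas the treated value below the floor was kept. Of the 23 lists, 12 had no member on a row with a single gene, and 0 of the 1 list with at least 5 measured members was called with limma camera.

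**Figure D3:**
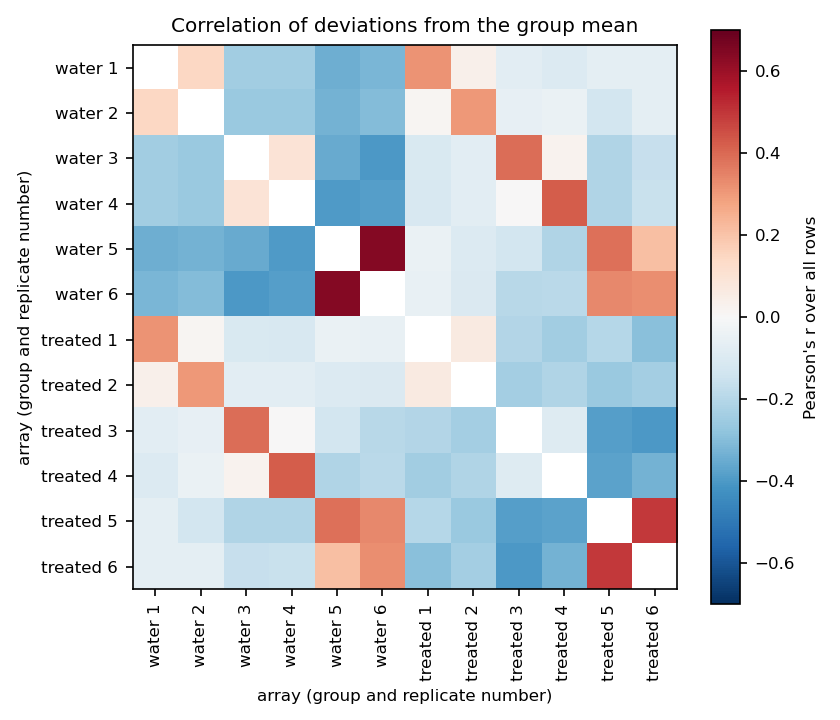
Pearson correlation, over all rows, of each pair of arrays in their deviations from the mean of their group (colour scale), with arrays ordered by group and replicate number on both axes and the diagonal left blank. Within a group, adjacent-numbered arrays correlate between -0.09 and 0.64 and other pairs between -0.40 and -0.20, and arrays of the same number in the 2 groups correlate between 0.30 and 0.43. Within a group, subtracting the shared mean makes even independent arrays correlate negatively.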

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

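The tests on sets of adjacent arrays and on other pairings, the fits without 1 set with their bound of 2 SE, and the within-array ratio below were chosen after the results they bear on had been seen. Among 88 groups of 6 values examined, 5 held an array far from the other 5, and chance gives about 5% of groups. For AT1G58230, water replicate 2 had a normalized log2 intensity of -6.26, with the others between -3.06 and -2.62. For AT4G31210, treated replicate 1 lay at -3.01 and the others between -2.03 and -1.66. For PSB27, water replicate 5 lay at 1.32 and the others between -0.19 and 0.33. For AT3G52960, treated replicate 3 lay at -2.39 and the others between -1.67 and -1.42. For GLDH, treated replicate 2 lay at -2.30 and the others between -1.36 and -0.88.

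The first pattern is the count of 1131 changed rows. Among 100 of the 462 splits of the arrays, 1 gave as many rows, the real one, and the highest other gave 17. Among the 32 splits that part all 6 number pairs, which differ from the real one in which array of a pair counts as treated, 1 gave as many and the highest other gave 2. These values argue against chance in how single arrays fell into the groups as the origin of the count. However, most of these splits break up the sets, and they treat the arrays as independent. On means of sets, 1 of 10 splits, the real one, gave 418 rows and the highest other gave 0, but 10 splits are too few for a share under 0.05.

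The second pattern is the drop from 1131 to 418 changed rows when arrays 1 and 2, 3 and 4, and 5 and 6 were averaged. In 6 of 6 adjacent pairs within a group, deviations correlated above those of all other pairs of that group, as shared handling or shared RNA would give. The sets were not alike, since replicates 5 and 6 correlated at 0.64 in water and 0.50 after treatment. The other adjacent pairs correlated between -0.09 and 0.14. Because the group mean includes the arrays compared, deviations of independent arrays of a group correlate negatively, so these values understate any sharing. Fewer values also cost calls, since in simulated data with independent arrays averaging lowered the share of rows changed by 1 on the log2 scale that were recovered from 60.4% to 39.2%, and of those changed by 0.5 from 21.4% to 7%. Fewer values alone are argued against as the whole origin of the drop, because 8 pairings of arrays from different sets, which leave as few values, gave 1048 to 1121 changed rows. Whether the arrays of a set are 1 RNA sample measured more than once cannot be told apart from a shared day, since the estimated correlation within a set of 0.511 would follow from either. No biological explanation was tested, because the labels give no group that follows the sets.

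The third pattern is that PSBW rose while PSAN, PSBY and LHB1B2 fell. The values argue against a single factor per array, which cannot move the log2 ratio of PSBW to the other 3 genes within an array: it rose by 1.63, with an SD of 0.411 within groups. As 100% of 1000 random picks of 1 changed row that rose and 3 that fell gave such a ratio too, it supports no other explanation. They also argue against an origin in 1 set alone, since 3 of 3 sets show these directions and each gene kept its direction by more than 2 SE without any 1 set (the least for LHB1B2, -0.51 ± 0.178 without set 1), but genes picked as changed would mostly do so, and this agreement adds no support for the pattern. In the test of the scalings, fixed beforehand, calls ended. PSBW had a log2 fold change of 0.65 ± 0.0925 (SE) with quantile normalization, 0.60 ± 0.231 as deposited, the lowest, and 0.70 ± 0.304 with median centring. LHB1B2 went from -0.65 ± 0.143 to -0.61 ± 0.213 with median centring. For both genes the size differed little, and the spread between arrays was smaller with quantile normalization. That step gave PSBW the same value on several arrays of a group. The SD of PSBW was 0.0705 in water and 0.215 after treatment, against 0.263 and 0.522 as deposited, so its call depends on this step. A scaling that differs with intensity therefore stays open, as do an intensity-dependent shift, since the 50 rows nearest to PSBW in brightness had a median log2 fold change of 0.047 with an SD of 0.76, and an effect of the treatment.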

How the results depend on the processing

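The analyses of sets, scaling before the floor and rows above 0 on all arrays were chosen after seeing the data. Of the counts of changed rows, those within 1.5 times of 1131 came from the table as deposited (1075), median centring (988), the floor at the 10th percentile (1136), the pseudocount (1176), no rows in the dimmest 25% (1086), the variance trend (1146), array weights (1142), the exact rank-sum test (1065), scaling before the floor (1017), rows above 0 on all arrays (1146) and the set as a fixed block (1388). Leaving out each array in turn gave 1010 to 1158 changed, 516 to 572 higher and 472 to 586 lower. With the replicate number as a block, 1252 rows changed (654 higher, 598 lower), and of the named genes this paired fit ended the calls of AT3G13120 and PIFI. Replicates 1 to 3 gave 699 (369 higher, 330 lower) and replicates 4 to 6 gave 621 (344 higher, 277 lower), with fewer samples. Means of sets gave 418 (236 higher, 182 lower), also with fewer values, and with the set as a block 211 (134 higher, 77 lower). Sets as random blocks gave 753 (344 lower), and the cause was not tested beyond the correlation within sets. Set 1 alone gave 733 (377 higher, 356 lower), set 2 alone 538 (292 higher, 246 lower) and set 3 alone 1227. No called gene changed direction in any alternative, and 0 lists were called in each alternative that gave a list test. No list test was made with the rank-sum test, nor without the dimmest 25% of rows or with rows above 0 on all arrays, where under 5 members of the list were left. Unknown signal over background limits what the dim rows can show.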

Other observations

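The lists and rows in this part were chosen after values had been seen. Among redox genes outside the fixed lists, AT5G58330, a plastid NADP-dependent malate dehydrogenase, rose from an intensity of 0.342 ± 0.0767 to 0.621 ± 0.113 (mean ± SD, n = 6 each). Its limma adjusted p was 0.00472, and 0.103 both on means of sets and with replicates 4 to 6 alone. SRX, sulfiredoxin, which restores overoxidized peroxiredoxins, rose from 0.343 ± 0.0212 to 0.453 ± 0.0826 (limma adjusted p 0.0375), a call lost on means of sets (0.169) and when any of 8 arrays was left out, with adjusted p of 0.0515 to 0.0789. CCS, a copper chaperone of superoxide dismutase, stood at 0.215 ± 0.0728 and 0.326 ± 0.0830 and did not pass (limma adjusted p 0.114). Pooled with the 3 fixed redox lists, 2 of 7 measured genes rose, 1 fell and 4 did not pass. PIFI, a plastid protein linked to the NDH complex, rose from 0.582 ± 0.208 to 0.973 ± 0.227 (limma adjusted p 0.0228), which was 0.0677 with the replicate number as a block, 0.0601 with array weights and 0.192 on means of sets. Its log2 fold change was 0.41 with replicates 1 to 3 alone (limma adjusted p 0.214) and 1.43 with replicates 4 to 6 alone (0.0618). The other 4 NDH genes did not pass. Among them, NdhN and CRR41 were each listed at 0 on 6 water and 5 treated arrays, so no change can be read for these genes. Of 5 calcium-signalling genes, GLR2.7, a glutamate receptor-like channel, rose 2.56-fold (limma adjusted p 0.00724, and 0.129 on means of sets) and 4 did not pass. With replicates 4 to 6 alone, GLR2.7 had a log2 fold change of 0.89 and missed the threshold (limma adjusted p 0.259). Of 6 factors of organelle RNA processing and translation, 0 passed in limma, and 3 had an unadjusted p under 0.05, as did 1460 of all 3439 rows. OTP85, among these 6, was listed at 0 on 6 water and 4 treated arrays. Camera called none of these lists nor the 7 pooled photosynthesis genes, with adjusted p between 0.550 and 0.651, or 0.716 and 0.772 with an estimated correlation.

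Several changed rows carry no single gene name. Row 3017, annotated to 3 small heat-shock protein genes, rose from 1.06 ± 0.216 to 3.88 ± 0.570 (limma adjusted p 2.21e-05, and 0.0131 on means of sets). Row 613, annotated to 2 light-harvesting-like genes, fell from 0.986 ± 0.169 to 0.478 ± 0.158 (limma adjusted p 0.000796, and 0.0354 on means of sets). Row 3455, annotated to 2 acyl carrier protein thioesterase genes, fell from 1.03 ± 0.0737 to 0.468 ± 0.0878 (limma adjusted p 1.33e-05, and 0.0128 on means of sets, but 0.0548 with the set as a block). Among the brightest rows, row 3656, unnamed here, rose from 13.0 ± 3.08 to 62.1 ± 10.5 (limma adjusted p 1.81e-06, and 0.00670 on means of sets), and row 1803, annotated to 2 genes, fell from 51.6 ± 2.70 to 24.7 ± 3.81 (limma adjusted p 0.000175, and 0.0396 on means of sets, but 0.0793 with the set as a block).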
